A study of Saccharomyces cerevisiae with 6 samples.

How the data were processed

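Polyadenylated RNA of 6 yeast libraries was measured by RNA sequencing, 2 libraries from each of 3 strains grown in rich glucose medium (YPD). Bowtie2 2.1.0, TopHat2 2.0.9 and Cufflinks 2.1.1 and the genome build R64 are named in the submitters' processing notes, which give neither the role nor the order of the tools. The deposited values are FPKM (fragments per kilobase of feature, scaled to the mapped total) with the bounds of a confidence interval, 1 table per library, per the file headers. Whether counting used the strand of the reads is not given in the sources used here, so reads of overlapping and antisense features cannot be told apart. Each table held 7126 features, of which 7051 had the status OK in every library, 61 were marked as having low data and 14 as having too many reads. Features without the status OK were left out. Gene identifiers were matched to the R64 annotation, where 6048 were found and 6036 had the same coordinates.

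The deposited FPKM of short features lay far above their own intervals. The median ratio of FPKM to the interval midpoint was 39.8 to 81.6 for features under 150 bp, 3.79 to 4.19 for 150 to 300 bp and 1.03 to 1.06 for 1200 bp or more. Features under 150 bp held 57.7% to 62.4% of the summed FPKM of a library, and RPL41A and RPL41B alone held 18.1% to 23.9%. Values of short features are therefore on another scale than those of long ones, and counts of changed genes were also computed over features of 300 bp or more. Depth was estimated from the interval bounds, which step in whole multiples of one amount per library. With a tolerance of 0.02, 85.5% to 87.7% of low bounds were whole multiples, and the step gave the number of mapped fragments. The FPKM values themselves were not converted to counts, and no count model was used. A value of 0 is described only as listed at 0.

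Samples were grouped by their titles into wild type, D8A and D8B. The unit of test was log2(FPKM + 1), so that fold changes of weakly expressed genes are understated. Features with a mean FPKM of at least 1 over the 6 libraries were kept, which left 6925. One linear model with a mean for each group was fitted to all 6 libraries with limma 3.58.1 in R 4.3.3, with moderated variances that follow the mean, 3 residual degrees of freedom and 4.7 prior degrees of freedom. Adjusted p-values are Benjamini-Hochberg values over all genes tested, two-sided, with a threshold of 0.05. The contrasts were the mean of both null strains against wild type, each null strain against wild type, and D8B against D8A. The last is also the test of whether the changes of the null strains differ. Genes listed at 0 in every library of a group add no spread there, and their errors rest on the spread of the other groups and on the prior.

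Gene lists were tested with camera of limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over 46 sets, made of 30 lists and the 16 nuclear chromosomes. Camera was repeated with an estimated correlation, and fry of limma, a rotation test, was run on each set without adjustment. The lists, the rule for naming genes, the tests and most alternatives were fixed before the data were examined. The lists covered targets of the oxidative stress factor Yap1, antioxidant enzymes, oxidative phosphorylation, the tricarboxylic acid cycle, mitochondrial ribosomes, mitochondrial import, haem synthesis, cytosolic ribosomes, ribosome biogenesis, the proteasome, chaperones, general stress genes, the iron regulon, glycolysis, glucose-repressed genes, DNA damage genes, ergosterol synthesis, Hap1 targets, adenine synthesis, sulphur amino acids, amino acid synthesis under Gcn4, the phosphate regulon, retrograde targets, drug resistance, histones, a-specific, alpha-specific and haploid-specific genes, meiosis and sporulation, and noncoding RNA. A list of genes of the mitochondrial genome could not be tested because all 55 of its features were listed at 0. Deleted genes and marker genes were listed for a label check, and they were kept in the tests of single genes, the counts and the chromosome sets of camera.

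The rule named the deleted and marker genes, and CCP1 and UTH1 as chromosome XI genes known from the study. Of the null strains against wild type it named the 8 largest rises and 8 largest falls with a mean FPKM of at least 10. For these the rule required an adjusted p under 0.05 for both strains together and for each strain. It further asked for the same direction in both strains and no overlap of libraries. It also named up to 4 called members of each list and any needed for a count of 5 or fewer, the 6 largest rises and 6 largest falls between D8B and D8A, and 4 rises and 4 falls on chromosome XI. For D8B against D8A the same rule was applied again to features of 300 bp or more, a choice made after the values were seen.

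The level of a chromosome in a library was the median log2(FPKM + 1) of its genes minus the median of the genes on the other 15 nuclear chromosomes, without deleted and marker genes. Its excess in a contrast was the same difference of median log2 fold changes. Levels were compared between groups with exact permutation tests, two-sided, whose smallest p is 0.067 for 4 libraries against 2 and 0.333 for 2 against 2. A regression on codon adaptation and length (splines, fitted on the other chromosomes) was used as a check, with codon weights from 137 ribosomal protein genes.

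The procedure was tested on simulated data for the mean of the null strains against wild type over 6925 genes, of which 200 were changed. It recovered 50% of the 2-fold and 91% of the 4-fold changes, and 10 of its 151 calls (6.6%) were false. A simulated excess of chromosome XI of 1 on the log2 scale came out as 1.00, and one of 0 as 0.004. Alternatives tried were pseudocounts of 0.1 and 5, no filter and a mean FPKM of at least 10, median centring, quantile normalization, each library left out, the replicate number as a block, limma without the trend and with robust variances, a 2-fold minimum, fits on only the groups compared, mean in place of median, chromosome ends within 30 kb left out, and chromosome XI left out. Added after seeing the data were features of 300 bp or more, interval midpoints, features with low data kept, the shallowest library left out together with short features, protein-coding genes only for the level of chromosome XI, and all alternatives for that level and for the excess of chromosome V. Named genes were recomputed under at most 17 of these alternatives, and for them every alternative or every setting means those run. Not run on named genes were limma without the trend, robust variances, the 2-fold minimum, fits on only the groups compared and chromosome XI left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.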

Results

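RNA sequencing profiles were collected from 3 strains of budding yeast, with 2 libraries each. One strain was labelled wild type, and its source label described it as having a single chromosome XI. The others, D8A and D8B, were labelled as lacking 8 thiol peroxidases, enzymes that reduce peroxides, and SRX1, the sulfiredoxin that repairs oxidised peroxiredoxins. The study's title concerns aneuploidy in cells without thiol peroxidases. Estimated depth was 9.15 M and 10.1 M fragments for wild type, 4.03 M and 8.06 M for D8A, and 14.2 M and 10.6 M for D8B. Between 108 and 258 features were listed at 0 per library, with the highest number in D8A replicate 1, the shallowest. Replicates correlated across genes with r = 0.976 for wild type, 0.938 for D8A and 0.973 for D8B, where genes are not independent replicates. D8A replicate 2 correlated more with every library of the other strains (r from 0.9414 to 0.9645) than with D8A replicate 1. D8A replicate 1 stood apart on the first principal component (39.9% of the variance), at 51.0 against a range of -32.3 to 9.24 for the other libraries. The labels do not say that replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. The genotype labels also give the wild type other auxotrophic markers than the null strains, so every comparison with wild type is between strains that differ in background as well as in the deleted genes.

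The deleted genes were examined first as a check of the labels. PRX1 (110 FPKM in wild type), GPX2 (45.6) and GPX1 (29.0) were listed at 0 in all 4 null libraries. HYR1, which the labels call GPX3, averaged 316 FPKM in wild type and 0.108 in the null libraries, DOT5 134 and 0.110, and AHP1 1548 and 0.572. TSA1 averaged 1876 ± 216 FPKM (SD, n = 2) in wild type and 8.04 ± 1.45 (SD, n = 4) in the null libraries, and TSA2 33.4 and 1.02. Each of these 8 genes fell in 4 of 4 null libraries in limma, with adjusted p from 3.47e-06 to 0.000147. SRX1 (YKL086W, chromosome XI, 278281 to 278664, R64) went against its label. The libraries labelled as deleted for it held 319 and 415 FPKM in D8A and 654 and 584 in D8B, against 64.8 ± 17.0 in wild type, a rise of 2.88 ± 0.23 (SE) on the log2 scale (limma adjusted p = 0.000571). Directions between null and wild-type libraries therefore rest on labels that 8 of the 9 deleted genes match and SRX1 does not. Among the marker genes, MET17, which the labels call MET15 and list as disrupted in the null strains, fell by 2.32 (limma adjusted p = 0.000776). It still averaged 103 FPKM in the null libraries, 19.8% of the wild-type mean. The labels give the wild type mutant alleles of ADE2, TRP1 and CAN1, so changes of these genes cannot be told apart from a difference in background. ADE2 rose by 1.48 and HIS3 by 1.40 (limma adjusted p = 0.00236 and 0.00471), and TRP1, which shares 265 bp with YDR008C, by 1.03 (adjusted p = 0.0275). Each of these 3 rises was lost without wild-type replicate 2, HIS3 and TRP1 also without wild-type replicate 1, and TRP1 without either D8B library, with limma adjusted p up to 0.277. LEU2, URA3 and CAN1 did not pass for the mean of both null strains (adjusted p = 0.105, 0.542 and 0.986). In D8A alone LEU2 passed as lower than wild type (60.2 against 139 FPKM, limma adjusted p = 0.0144). In D8B LEU2 did not pass (0.07, adjusted p = 0.892), nor did its difference between D8B and D8A (adjusted p = 0.0601). URA3 passed as lower in D8B (-1.21, limma adjusted p = 0.0318) and not in D8A (0.71, adjusted p = 0.17). CAN1 passed in neither strain (adjusted p = 0.273 in D8A and 0.241 in D8B).

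**Figure D1:**
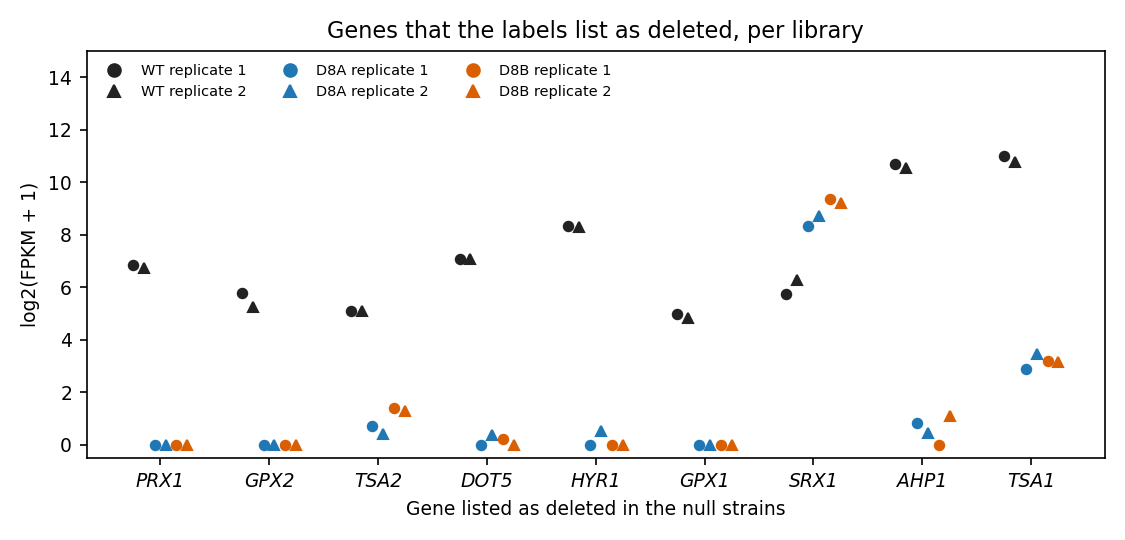
The 9 genes labelled as deleted, as log2(FPKM + 1), with 1 point per library in the 3 strains. For 8 genes the 4 null libraries lie far below the wild-type libraries, at 6.42 to 9.94 FPKM for TSA1 and lower for the others. For SRX1 they lie between 319 and 654 FPKM, above the wild-type libraries.

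The comparison of the null strains with wild type asked which genes differ in libraries labelled as lacking the thiol peroxidases. TRX2 (YGR209C), the thioredoxin induced by oxidative stress, rose from 1076 ± 204 FPKM (SD, n = 2) in wild type to 5612 ± 1686 (SD, n = 4), a log2 change of 2.35 ± 0.29 (SE; limma adjusted p = 0.00347). CHA1 (YCL064C), a catabolic serine and threonine deaminase, rose from 8.73 ± 1.80 to 290 ± 99.9 FPKM, by 4.85 (limma adjusted p = 2.24e-05). PIR3 (YKL163W), a cell wall protein, fell by 3.67, from 456 ± 127 to 34.3 ± 3.41 FPKM (limma adjusted p = 8.75e-05). AIF1 (YNR074C), listed at 0 and 0.106 FPKM in wild type, held 36.5 to 63.8 FPKM in the null libraries, and COS12 (YGL263W), a member of a subtelomeric family whose copies can share reads, was listed at 0 in wild type and held 27.5 to 47.0 FPKM. Further rises were those of IZH4 (3.06), YDR274C (2.97), GAS2 (2.88) and YMR320W (2.75). Further falls were YCR099C (-3.89), YCR101C (-3.56), YNR066C (-3.43) and YCR100C (-3.34), of which YCR099C and YCR100C overlap by 29 bp. YDR034W-B (156 bp, -3.49) and YAR035C-A (81 bp, listed at 0 in D8A) lie in the range where FPKM is inflated, and YLR302C, listed at 0 in all 4 null libraries, overlaps MET17 by 12 bp. The rule for naming required all 4 null libraries beyond both wild-type libraries and a pass in each strain, so neither is a separate result. The limma adjusted p of the genes named here was up to 0.00347. The TRX2 call was lost only without wild-type replicate 2 (adjusted p = 0.0718).

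In all, 447 of 6925 features passed limma's test at an adjusted p of 0.05, 107 higher and 340 lower in the null strains, and 404 of them were 300 bp or longer. The count (genes changed, D8 mean vs WT, where D8 mean stands for both null strains) depended on single libraries. It was 201 without wild-type replicate 1, 114 without wild-type replicate 2 and 671 without D8A replicate 2. It was 685 with quantile normalization, 741 with robust variances and 948 when only features of 300 bp or more were fitted.

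Genes of oxidative defence under Yap1 were higher as a group in the null strains. Of 15 measured Yap1 targets, 3 rose (TRX2, CCP1 and AAD4) and 0 fell, 8 rose when adjusted over the list alone, and the median was 0.55 (camera adjusted p = 6.64e-05, and adjusted p = 0.998 with an estimated correlation). AAD4 (0.81) belongs to a family of similar genes that can share reads. Of 23 antioxidant enzymes, some of them also Yap1 targets (TRX2, CCP1, TRR1, GSH1, GSH2 and GLR1), TRX2, CCP1 and SOD1 (1.30) rose, 5 when adjusted over the list alone, and the list did not pass (median 0.15, camera adjusted p = 0.284). SOD1 (limma adjusted p = 0.0357) no longer passed when any of 5 libraries was left out (highest adjusted p = 0.395), nor AAD4 (adjusted p = 0.0256) when either wild-type or either D8B library was (highest adjusted p = 0.284).

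Genes of respiration were lower in the libraries labelled null. Of 40 nuclear genes of oxidative phosphorylation, 6 fell and 0 rose, 12 fell when adjusted over the list alone, and the median was -0.68 (camera adjusted p = 1.04e-08, and adjusted p = 0.998 with an estimated correlation). CYC7 (-1.95), the second cytochrome c isoform, NDE1 (-1.72), an external NADH dehydrogenase, SDH1 (-1.42), a subunit of succinate dehydrogenase, and COX5B (-1.19) led these falls (limma adjusted p = 0.00137, 0.00269, 0.0123 and 0.0231). The median level of the list above all genes was 3.40 and 3.20 in wild type, 2.94 and 3.30 in D8A and 2.73 and 2.39 in D8B, so that D8A replicate 2 lay within the wild-type range. Hap1 targets, which respond to a factor that differs between laboratory strains, had 3 falls among 9 members (CYC7, CYT1 and CYB2), 5 when adjusted over the list alone, and a median of -0.67 (camera adjusted p = 0.00851, and adjusted p = 0.998 with an estimated correlation). Glucose-repressed genes had 1 fall among 14 (IDP2, -1.14), 4 falls and 1 rise when adjusted over the list alone, and a median of -0.49 (camera adjusted p = 0.0164, and adjusted p = 0.998 with an estimated correlation). In the tricarboxylic acid cycle only ACO1 of 15 genes passed (-1.15), 4 fell and 1 rose when adjusted over the list alone, and the list did not pass (adjusted p = 0.124). Among 7 retrograde targets CIT2 rose (1.00), PDH1 (-1.38) and ACO1 fell, 1 rose and 4 fell when adjusted over the list alone, and the list did not pass (adjusted p = 0.110). Mitochondrial ribosomes (54 genes), mitochondrial import (17) and haem synthesis (8) had 0 calls in limma over all genes and 0 when adjusted over the list alone, against 3, 1 and 1 at an unadjusted p under 0.05, and did not pass camera (adjusted p = 0.0887, 0.245 and 0.986). The call of CYC7 was kept in every alternative, whereas without wild-type replicate 2 NDE1, SDH1, COX5B, CYT1, CYB2, IDP2, ACO1, PDH1 and CIT2 were lost, all but NDE1 also without wild-type replicate 1, with limma adjusted p up to 0.323. COX5B was also lost without D8A replicate 1, ACO1 without D8B replicate 1, CYT1 without either D8B library, and CYB2 and CIT2 without D8B replicate 2. Each against wild type, D8B passed camera for oxidative phosphorylation, Hap1 targets and glucose-repressed genes (adjusted p = 2.89e-16, 0.000808 and 0.00370, and each adjusted p = 0.992 with an estimated correlation) and D8A did not (adjusted p = 0.0531, 0.172 and 0.172). The difference between the strains passed for oxidative phosphorylation and Hap1 targets (camera adjusted p = 5.38e-18 and 0.00482, and adjusted p = 0.893 and 0.781 with an estimated correlation) but not for glucose-repressed genes (adjusted p = 0.0889). Mitochondrial ribosomes and the tricarboxylic acid cycle also passed in D8B against wild type (medians -0.27 and -0.35, camera adjusted p = 0.000384 and 0.0258). With an estimated correlation both had adjusted p = 0.992, and neither passed in D8A (adjusted p = 0.871 and 0.528). Between the strains mitochondrial ribosomes passed (camera adjusted p = 5.9e-08, and adjusted p = 0.98 with an estimated correlation) and the cycle did not (adjusted p = 0.137). The list of glucose-repressed genes no longer passed without wild-type replicate 2 (highest camera adjusted p = 0.110).

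Amino acid synthesis was lower. Of 18 Gcn4-controlled biosynthetic genes, 11 fell and 1 (LYS20) rose, 14 and 1 when adjusted over the list alone, with a median of -1.05 (camera adjusted p = 1.71e-08, and adjusted p = 0.998 with an estimated correlation). ARG4 fell by 2.21 (663 ± 43.9 to 144 ± 28.0 FPKM), ILV2 by 1.86 and ARG1 by 1.61 (limma adjusted p = 0.00172, 0.00172 and 0.00307). Of 16 genes of sulphur amino acids, 6 fell and 0 rose, 7 fell when adjusted over the list alone, with a median of -0.73 (camera adjusted p = 2.51e-05, and adjusted p = 0.998 with an estimated correlation). MET16 (-1.81), STR3 (-1.56), MET6 (-1.46) and MET10 (-1.28) led them (limma adjusted p = 0.00265, 0.0106, 0.0204 and 0.0173). The null strains are labelled met15 and the wild type is not, so this list moves with a marker of the background. Ergosterol synthesis had 2 falls among 23 genes, ERG28 (-1.22) and ERG2 (-0.91), also 2 when adjusted over the list alone, and a median of -0.29 (camera adjusted p = 0.0224, and adjusted p = 0.998 with an estimated correlation). In D8A alone the ergosterol median was -0.52 (camera adjusted p = 3.54e-06, and adjusted p = 0.503 with an estimated correlation), whereas D8B lay near wild type, at -0.02 with 2 rises and 0 falls (adjusted p = 0.966), and ERG28 and ERG2 passed in D8A but not in D8B. The difference between the strains passed in limma for ERG28 (adjusted p = 0.0369) and not for ERG2 (adjusted p = 0.0841). The ergosterol list no longer passed without either wild-type library, D8A replicate 2 or D8B replicate 1 (highest camera adjusted p = 0.170). ARG4, ILV2 and MET16 kept their calls in every alternative, whereas ARG1 and MET10 were lost without wild-type replicate 2, and STR3, MET6, ERG28 and ERG2 without either wild-type library, with limma adjusted p up to 0.357. ERG2 was also lost without D8A replicate 1 or either D8B library.

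Small shifts were spread over the proteasome, with a median of 0.34 over 31 genes, ribosome biogenesis, with 0.34 over 30, and cytosolic ribosomes, with -0.26 over 137. In each of these 3 lists 0 members passed in limma over all genes or when adjusted over the list alone, against 5, 3 and 3 at an unadjusted p under 0.05. Their camera adjusted p was 0.000140, 0.000544 and 0.000153, and each list had adjusted p = 0.998 with an estimated correlation. For the cytosolic ribosomes the median was -0.46 in D8A (camera adjusted p = 7.04e-09, and adjusted p = 0.989 with an estimated correlation) and -0.05 in D8B (adjusted p = 0.568), where replicate 1 lay above and replicate 2 below both wild-type libraries. D8B exceeded D8A by a median of 0.41 (camera adjusted p = 6.13e-11, and adjusted p = 0.98 with an estimated correlation), a call lost without D8B replicate 1 (highest adjusted p = 0.215). The cytosolic ribosomes no longer passed without wild-type replicate 1 or D8B replicate 2 (highest camera adjusted p = 0.609). Of the other lists, general stress genes had HXK1 higher (1.62) and HSP12 (-2.37) and GPH1 (-1.75) lower among 20, with 4 rises and 6 falls when adjusted over the list alone. The phosphate regulon had PHM6 higher (1.08) and GIT1 (-1.68) and PHM8 (-0.97) lower among 14, and drug resistance PDR3 higher (0.96) and PDR5 lower (-0.90) among 7, with unchanged counts when adjusted over the list alone. ISU2 (0.74) was the only call among 25 genes of the iron regulon, with 0 when adjusted over the list alone. In D8B against wild type the iron regulon passed higher (median 0.96, camera adjusted p = 7.09e-07). General stress genes (-0.46) and the phosphate regulon (-0.33) passed lower there (camera adjusted p = 0.0258 each). With an estimated correlation each had adjusted p = 0.992. In D8A they did not pass (medians -0.315, -0.03 and 0.28, adjusted p = 0.172, 0.858 and 0.172). For the mean of both null strains none of the 4 lists, drug resistance included, passed camera (adjusted p = 0.578, 0.977, 0.661 and 0.0887). All 9 genes named from them lost their calls without wild-type replicate 2, and all but HXK1 and GPH1 also without wild-type replicate 1, with limma adjusted p up to 0.460. PHM6 (also without either D8A library or D8B replicate 1), GIT1 (D8B replicate 2), PHM8 and ISU2 (either D8B library) and PDR5 (D8A replicate 1 or D8B replicate 1) depended on further libraries. PHM6 and PHM8 were also lost with a pseudocount of 0.1, without the filter and with features of low data kept, and PHM6 with centred or quantile-normalized libraries. Chaperones (19), glycolysis (16) and histones (8) had 0 calls in limma, over all genes or when adjusted over the list alone, and 3, 0 and 0 at an unadjusted p under 0.05, while DNA damage genes (13) and adenine synthesis (10) had 0 over all genes, 1 rise each when adjusted over the list alone and 1 and 3 at an unadjusted p under 0.05 (camera adjusted p = 0.986, 0.997, 0.887, 0.878 and 0.169). Adenine synthesis passed higher in D8B against wild type (camera adjusted p = 0.0258, and adjusted p = 0.992 with an estimated correlation) and not in D8A (adjusted p = 0.733).

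Markers of other cell types and states did not pass as lists for the mean of both null strains. The a-specific (7) and alpha-specific (4) genes had 0 calls in limma, also when adjusted over the list alone, and 1 each at an unadjusted p under 0.05 (camera adjusted p = 0.977 and 0.872), and for the a-specific genes the median of 0.10 and the mean of -0.14 differ in sign. Of 8 haploid-specific genes HO rose (1.05) and FUS3 (-1.02) and RME1 (-0.95) fell (camera adjusted p = 0.476). Among 10 genes of meiosis and sporulation SPS1 (-1.37) and DIT1 (-0.96) fell (adjusted p = 0.110), and these counts were unchanged when adjusted over the list alone. In D8B against wild type meiosis and sporulation passed lower (median -0.34, camera adjusted p = 0.0255, and adjusted p = 0.992 with an estimated correlation). In D8A this list did not pass (adjusted p = 0.526). Of 86 noncoding RNA features snR44 fell (-1.14), but it lies within RPS22B, and 0 passed in limma when adjusted over the list alone, with 14 at an unadjusted p under 0.05 (camera adjusted p = 0.0887). The calls of HO, FUS3, RME1, SPS1, DIT1 and snR44 were lost without either wild-type library, and each of them also without at least 1 null library, with limma adjusted p up to 0.363.

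**Figure D2:**
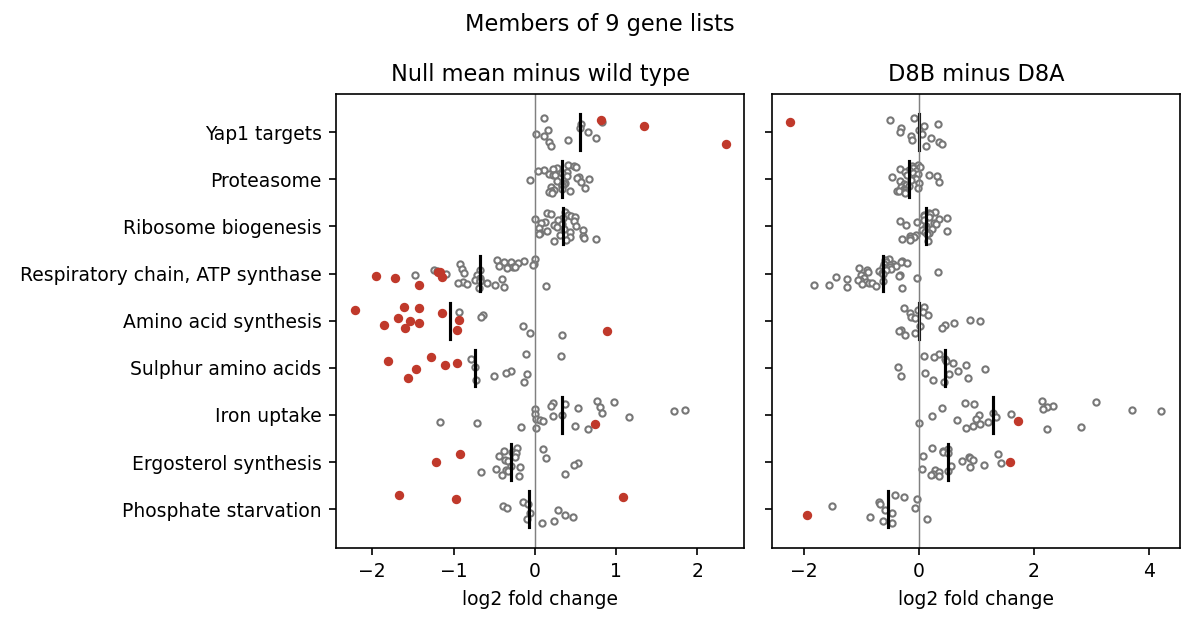
Log2 fold changes of the members of 9 gene lists, with 1 point per gene and a black bar at the median, for the null strains minus wild type (left) and D8B minus D8A (right). Red filled points passed limma's test at an adjusted p of 0.05 and open grey points did not. On the left the medians of the respiratory genes (-0.68) and amino acid synthesis (-1.05) lie below 0 and that of Yap1 targets (0.55) above, and on the right iron uptake (1.29) lies above 0.

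Chromosome XI was examined because the title names aneuploidy and the wild-type label a single copy of this chromosome. Its 364 genes, without deleted and marker genes, stood about 2-fold above the genes of the other chromosomes in all 6 libraries. The level was 1.03 ± 0.05 on the log2 scale (SD, n = 2; 2.04-fold) in the libraries labelled wild type, 1.04 ± 0.002 in D8A and 1.10 ± 0.07 in D8B. The other 15 chromosomes had mean levels over the 6 libraries from -0.58 (chromosome I) to 0.28 (chromosome V). The null libraries exceeded the wild-type libraries by 0.04 (exact permutation p = 0.533, where 0.067 is the smallest possible), D8A by 0.01 (exact permutation p = 1) and D8B by 0.08 (exact permutation p = 0.667, where 0.333 is the smallest possible). In fold changes the chromosome XI excess was 0.03 for both strains together and 0.02 for each (camera adjusted p = 0.997, 0.932 and 0.966), and its sign turned with means in place of medians.

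**Figure D3:**
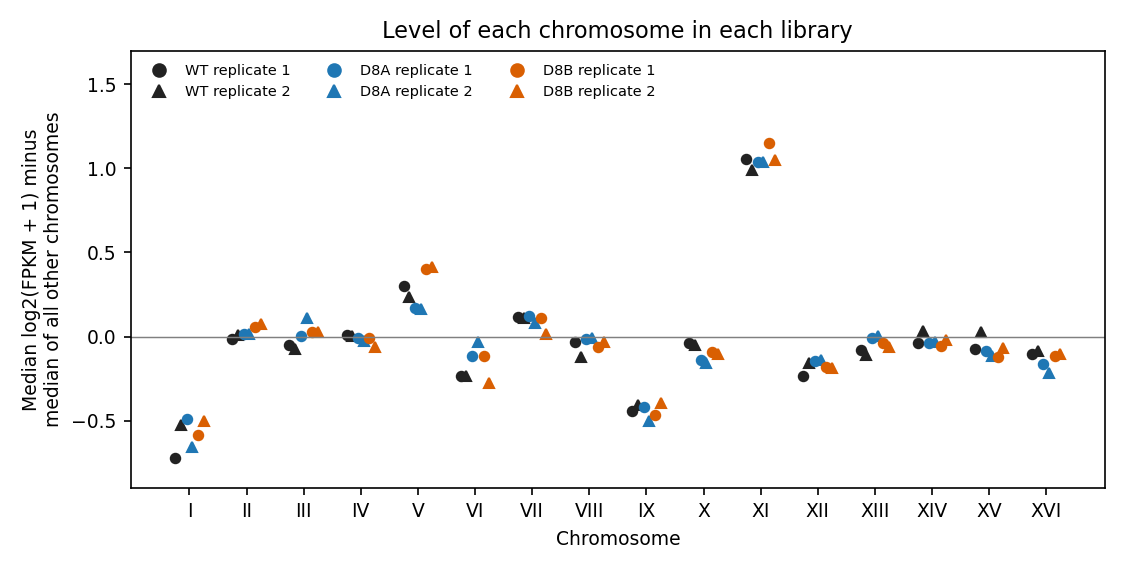
Level of each nuclear chromosome, the median log2(FPKM + 1) of its genes minus that of all other chromosomes, with 1 point per library. Chromosome XI lies between 0.99 and 1.15 in all 6 libraries, while the mean of every other chromosome lies at or below 0.28.

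Single genes of chromosome XI differed between the strains in both directions. CCP1 (YKR066C, 566113 to 567198), the mitochondrial cytochrome c peroxidase, rose by 1.35 ± 0.27 (SE), from 185 ± 16.7 to 482 ± 117 FPKM (limma adjusted p = 0.0260). UTH1 (YKR042W, 519527 to 520624), a protein of the mitochondrial outer membrane and cell wall, rose by 1.42 ± 0.27, from 385 ± 68.3 to 1046 ± 242 FPKM (limma adjusted p = 0.0227). Both were higher in 4 of 4 null libraries. Against wild type CCP1 passed in D8B (limma adjusted p = 0.0474) and not in D8A (adjusted p = 0.062). UTH1 passed in D8A (limma adjusted p = 0.0319) and not in D8B (adjusted p = 0.0713). Neither gene passed between D8B and D8A (limma adjusted p = 0.946 and 0.775). TGL4 (1.02), a lipase, and YSR3 (0.95) rose as well, while PIR3 (-3.67), GAP1 (-2.94), the general amino acid permease, SRL3 (-2.77) and KDX1 (-2.68) had the largest falls apart from the deleted GPX1 (limma adjusted p up to 0.0150 for these 6 genes). Of 366 features of the chromosome, with SRX1 and GPX1 counted, 6 rose and 23 fell. The CCP1 call was lost without either wild-type library or D8B replicate 1, and the UTH1 call without either wild-type library or D8A replicate 1 and with quantile normalization, with limma adjusted p up to 0.287 and 0.218. TGL4 and YSR3 were lost without either wild-type library (highest adjusted p = 0.196 and 0.204), while PIR3, GAP1, SRL3 and KDX1 were kept in every alternative.

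**Figure D4:**
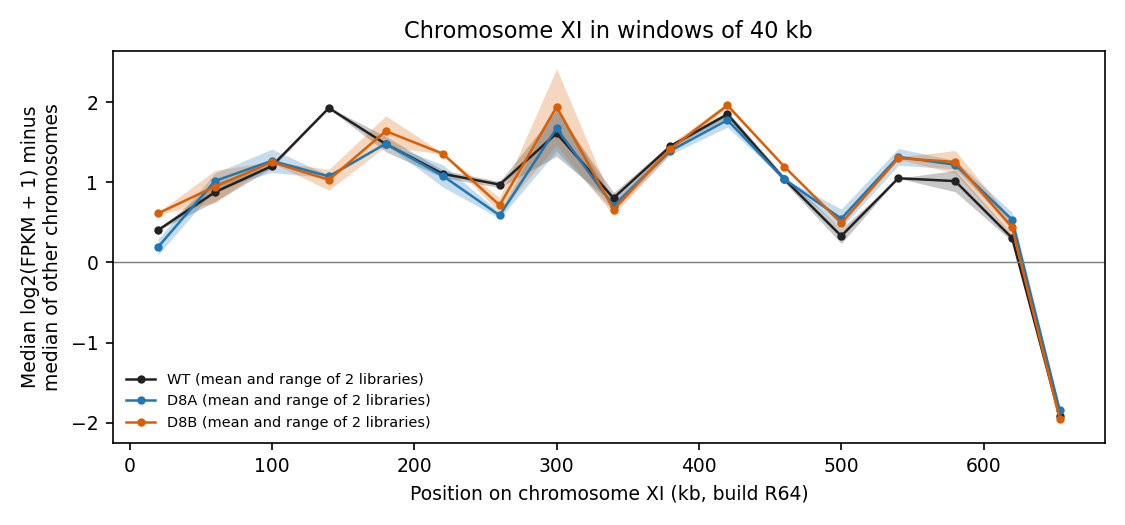
Level of chromosome XI in windows of 40 kb along the chromosome (R64 coordinates), 1 line per strain for the mean and a band for the range of its 2 libraries. Between 120001 and 160000 wild type lies at 1.93 and D8A and D8B at 1.07 and 1.03, although the median log2 fold change of the genes there was -0.07, and between 240001 and 280000 wild type lies at 0.97 and the null strains at 0.59 and 0.71.

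Each null strain was also compared with wild type on its own. In D8A 350 features passed in limma, 85 higher and 265 lower, and in D8B 339, 84 higher and 255 lower. CHA1 rose by 5.22 in D8A and 4.48 in D8B, and TRX2 by 2.15 and 2.55, while PIR3 fell by 3.78 and 3.56 (limma adjusted p up to 0.0120). The rule that named these genes required a pass in each strain. Both strains shared 37 higher and 169 lower features with 0 opposite, where independent lists would share 1.03 and 9.76. The fold changes correlated across genes with r = 0.627, where unchanged groups simulated against the same controls gave 0.50, and had the same sign for 73.9% of genes against 66.6%. Their covariance was 0.326 against a simulated 0.0655, a difference of 0.260, and part of the excess overlap may come from the shared controls, which are too few to be split. The 8 deleted genes that fell passed as lower in both strains and match their labels. MET17 passed as lower in both as well, in the direction of its label, but kept 19.8% of its wild-type mean. These genes were kept in the overlap, correlation and covariance, so part of each follows from the genotype. The D8A count (genes changed, D8A vs WT) was 142 and 90 without wild-type replicate 1 or 2 and 198 without D8A replicate 1. The D8B count (genes changed, D8B vs WT) was 170 and 98 without wild-type replicate 1 or 2 and 184 and 127 without D8B replicate 1 or 2. In D8A 7 sets passed camera, 3 higher and 4 lower, and in D8B 15 sets, 5 higher and 10 lower, of which none held with an estimated correlation (lowest adjusted p = 0.503 and 0.992 with an estimated correlation).

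D8B was compared with D8A because both carry the same genotype label. Iron uptake genes were higher in D8B: 25 of 25 members lay above 0 with a median of 1.29, although only FTR1, the iron permease, passed over all genes (1.74, limma adjusted p = 0.0369), and 22 rose when adjusted over the list alone (camera adjusted p = 2.76e-17, and adjusted p = 0.781 with an estimated correlation). The D8A libraries differed from each other, with a median level of the list relative to all genes of 0.78 and -1.08, against 1.47 and 1.75 in D8B and 0.57 and 0.62 in wild type. Ergosterol genes were higher, 23 of 23 above 0 with a median of 0.52, of which ERG28 passed (1.60, limma adjusted p = 0.0369) and 10 when adjusted over the list alone (camera adjusted p = 6.13e-11, and adjusted p = 0.212 with an estimated correlation). Oxidative phosphorylation was lower, 39 of 40 genes below 0 with a median of -0.62, 0 passing in limma over all genes, 15 at an unadjusted p under 0.05 and 9 when adjusted over the list alone (camera adjusted p = 5.38e-18, and adjusted p = 0.893 with an estimated correlation). The phosphate regulon was lower, 13 of 14 below 0 with a median of -0.52, of which PHO89, a sodium-phosphate transporter, passed (-1.94, limma adjusted p = 0.0226) and 3 when adjusted over the list alone (camera adjusted p = 1.23e-07, and adjusted p = 0.212 with an estimated correlation).

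Among single genes, TIR1 (2.97), a cell wall mannoprotein, was higher in D8B, and ARO10 (-2.24), a decarboxylase of amino acid catabolism, and the neighbouring aryl-alcohol dehydrogenase relatives AAD6 (-2.23) and AAD16 (-2.12) were lower (limma adjusted p = 0.0226, 0.0212, 0.0196 and 0.0226). URA3, the marker of the prx1 and gpx1 deletions, held 209 and 294 FPKM in D8A and 70.5 and 59.1 in D8B (-1.92, limma adjusted p = 0.0233). YCL021W-A held 61.3 and 60.5 FPKM in D8A and 0.405 and 0 in D8B, whereas YBR012C and YBR013C were listed at 0 in both D8A libraries and held 54.9 to 112 FPKM in D8B. In all, 23 features passed in limma, 15 higher and 8 lower, of which 5 were under 150 bp. The count (genes changed, D8B vs D8A) was 42 without D8A replicate 1, 104 without D8A replicate 2 and 10 without D8B replicate 2, and 197 over features of 300 bp or more. With quantile normalization 50% of the calls were higher, against 65.2% as deposited. The calls of TIR1, ARO10, PHO89, FTR1 and URA3 were lost without either D8B library, with limma adjusted p up to 0.165, 0.0944, 0.132, 0.170 and 0.161, FTR1 and URA3 also without either wild-type library. AAD6 and AAD16 were lost without D8A replicate 1 or either D8B library (highest adjusted p = 0.105 and 0.140), and these and TIR1 and FTR1 also with centred or quantile-normalized libraries.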

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

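The tests with codon adaptation on chromosome XI were chosen before their results were seen. The other tests weighed in this part were chosen only after the result was seen: those of feature length, exchanged libraries, SRX1 and chromosome V.

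The 2-fold level of chromosome XI in libraries labelled as having a single copy was the first pattern. The level lay at 1.05 or more in each library over features of 300 bp or more, which argues against a length effect of FPKM, and the regression on codon adaptation and length removed at most 4% of it in wild type, which argues against genes of a kind expressed high from 1 copy. An exchange of null and wild-type libraries is argued against by TSA1, whose lowest wild-type value was 173 times the highest null value. The level after the regression was still 1.02 in the lower wild-type library, and the other chromosomes reached at most 0.25 in any library, so the values are consistent with the hypothesis that the cells of the wild-type libraries also carried 2 copies of chromosome XI. The genotype label lists HIS3 and KanMX6 at the same site of this chromosome, which 2 copies with a different marker each would allow. FPKM does not count DNA copies, however, and a source label that belongs to another strain stays open as an explanation. Since wild-type and null libraries stood at like levels, the chromosome XI excess between them does not show whether null strains carried an extra copy.

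SRX1 was higher in the libraries whose labels list it as deleted. Its neighbours CYT2 and MDH1 changed by at most 0.18 on the log2 scale, which argues against reads of a neighbouring gene. The lowest null library held 492% of the wild-type mean, which is the pattern itself and leaves reads of a transcribed remnant open, because FPKM does not show where in the gene the reads lie. SRX1 mean FPKM was 7.61 times that of wild type, but whether an intact SRX1 lay beside a deleted copy or the gene was never deleted cannot be told apart, because FPKM shows transcription in both cases. SRX1 lies on chromosome XI, as does GPX1, which was listed at 0 in all 4 null libraries.

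Chromosome V genes were slightly higher in D8B than in D8A, by a median of 0.23 (camera adjusted p = 6.43e-05, but adjusted p = 0.98 with an estimated correlation). Against wild type the excess over the other chromosomes was 0.127 in D8B and -0.081 in D8A, and neither passed camera (adjusted p = 0.0796 and 0.545). Between D8B and D8A, 71% of chromosome V genes lay above the median fold change of all genes, which argues against a few genes as the cause. The excess over the other chromosomes was 0.17 as deposited and 0.16 with quantile normalization. A shift common to all genes of a library cancels in this difference, so these values cannot weigh normalization between libraries as a cause. All windows of 40 kb (15 of 15, 100%) lay above the median fold change of all genes (0.066), the lowest at 0.069. That would be needed if some D8B cells carried an extra chromosome V. Both D8B libraries, at 0.40 and 0.42, lay above the other 4, at 0.16 to 0.30 (exact permutation p = 0.067, the smallest possible). Over the 279 genes with codon data D8B replicates 1 and 2 lay at 0.22 and 0.31 and the other libraries at -0.03 to 0.16, but after regression on codon adaptation and length D8B replicate 2 lay at 0.25 (1.19-fold) and replicate 1 at 0.004, with the others from -0.11 to 0.004, and without D8B replicate 2 the excess fell to 0.084 and no longer passed (chromosome V excess, D8B vs D8A). Whether D8B replicate 2 alone or both D8B libraries carry the shift cannot be told apart, since the values before and after the regression differ on this, and an extra chromosome in a share of the cells and a technical shift both stay open.

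The remaining differences between D8B and D8A come from limma's test of the difference itself and are given as values. Features under 150 bp, where FPKM is inflated, were higher in D8B: YHL015W-A by 7.98, YGR204C-A by 6.99, YAR035C-A by 6.97 and YPL152W-A by 6.07. All 4 were listed at 0 in both D8A libraries, so these fitted changes depend on the pseudocount and are no measure of size. The same holds for YBR013C (6.32) and YBR012C (6.31), and for YCL021W-A (-5.71), listed at 0 in 1 D8B library. Among other genes TIR1 (2.97), YOR203W (2.20), which overlaps HIS3 and DED1, YGR114C (1.92), which overlaps SPT6, FTR1 (1.74) and ERG28 (1.60) were higher, and URA3 (-1.92), PHO89 (-1.94), AAD16 (-2.12), AAD6 (-2.23) and ARO10 (-2.24) were lower. The calls of YOR203W and YGR114C were lost without either D8B library (highest limma adjusted p = 0.140 and 0.108), that of YHL015W-A with interval midpoints (adjusted p = 0.0736), and that of YPL152W-A with interval midpoints and with quantile normalization (highest adjusted p = 0.0655).

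Gene lists that differed by camera were the iron regulon (median 1.29), ergosterol (0.52), histones (0.52), sulphur amino acids (0.45), cytosolic ribosomes (0.41), adenine synthesis (0.35) and glycolysis (0.28), all higher in D8B. Lower were the proteasome (-0.16), meiosis and sporulation (-0.22), mitochondrial ribosomes (-0.28), general stress genes (-0.31), Hap1 targets (-0.47), the phosphate regulon (-0.52) and oxidative phosphorylation (-0.62). Without 1 library the calls of adenine synthesis (both wild-type libraries, D8A replicate 2, D8B replicate 2), glycolysis (both wild-type libraries, D8A replicate 2, D8B replicate 1), histones (every library but D8B replicate 2), meiosis and sporulation (both D8A libraries, D8B replicate 1), sulphur amino acids and the proteasome (D8A replicate 2, D8B replicate 2) and cytosolic ribosomes (D8B replicate 1) were lost, with camera adjusted p up to 0.526, 0.976, 0.825, 0.134, 0.153, 0.603 and 0.215 over all alternatives. No list held with an estimated correlation, where the lowest adjusted p was 0.212.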

How the results depend on the processing

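Alternatives chosen only after seeing the data were those with features of 300 bp or more, interval midpoints, features with low data kept, the shallowest library and short features left out, and all alternatives for the level of chromosome XI and the excess of chromosome V. Counts are given in the order genes changed, D8 mean vs WT, genes changed, D8A vs WT, genes changed, D8B vs WT, and genes changed, D8B vs D8A, where D8 mean stands for both null strains and the main counts were 447, 350, 339 and 23. Robust variances gave 741, 616, 632 and 116, features of 300 bp or more 948, 801, 817 and 197, and quantile normalization 685 for both null strains. Interval midpoints gave 671 for both, 595 for D8B and 84 between the null strains, and leaving out the shallowest library with short features 774, 824 and 110. Of the 447 genes, 443, 404, 417, 427 and 404 were among the calls of these settings, in the order given. With 1 library left out the counts ranged from 114 to 671, 90 to 473, 98 to 477 and 10 to 104, where fewer samples remain and a lone sample is assumed to vary like the other groups. For the other changes of counts the cause was not tested.

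The replicate number as a block gave 187 for D8A, 213 for D8B and 9 between the null strains, and moved no other count by over 1.5 times. Numbers did not pair the libraries: same-numbered deviations correlated at -0.148, 0.332 and -0.254.

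The chromosome XI excess, D8 mean vs WT, chromosome XI excess, D8A vs WT, and chromosome XI excess, D8B vs WT, turned to -0.041, -0.032 and -0.051 with means in place of medians, and the cause was not tested; it passed no test under any setting run. The level of chromosome XI, 1.05, was 0.98 with a pseudocount of 5, 0.91 with a mean FPKM of at least 10 and 0.97 with means, and 1.04 to 1.07 with a library left out; the cause was not tested. The chromosome V excess, D8B vs D8A, lost its call at the preset correlation only without D8B replicate 2 (0.084), and with an estimated correlation as well.

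With an estimated correlation 0 of the 10 sets for both null strains and 0 of the 15 between them passed, as a larger correlation widens the test by construction. Leaving out a library gave 9 to 12 and 9 to 14 sets. Yap1 targets, oxidative phosphorylation, Gcn4-controlled genes, sulphur amino acids, the proteasome, ribosome biogenesis and Hap1 targets passed in all 18 settings with the preset correlation. Between the null strains ergosterol, the iron regulon, oxidative phosphorylation, the phosphate regulon, mitochondrial ribosomes, general stress genes and Hap1 targets did so. Glycolysis passed in 7, histones in 8 and adenine synthesis in 11.

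For 92 results on named genes 1547 alternative values were computed; 1359 kept direction and side of the threshold, 184 lost the call, 2 gained it and 2 reversed. The reversals were CAN1, whose log2 change of 0.01 was -0.12 without D8A replicate 2 and ranged from -0.147 (without D8B replicate 2) to 0.166 with a library left out. Of 89 called results 37 were kept in every setting, TSA1, SRX1, CHA1, PIR3, GAP1, ARG4, ILV2 and CYC7 among them, and 22 were lost only without a library. Depth limits weak genes most in D8A replicate 1, with 4.03 M fragments.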

Other observations

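All tests in this part were chosen only after the result was seen.

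Several genes of cell wall integrity were lower in the null libraries beyond PIR3. SED1, an abundant cell wall protein, went from 3478 FPKM in wild type to 747 in the null libraries (-2.21, limma adjusted p = 0.00522), CWP1 from 1094 to 232 (-2.33, adjusted p = 0.00978), YLR194C from 627 to 133 (-2.25, adjusted p = 0.00116) and PRM5 from 183 to 39.6 (-2.18, adjusted p = 0.00208). SLT2, the kinase of the cell wall integrity pathway, fell by 1.25 (adjusted p = 0.00839) and TIP1 rose by 1.87 (adjusted p = 0.00325). The hypothesis that cell wall integrity targets are lower as a group was examined on a list of 25 genes, which was written after some of its members had been seen to fall and is therefore not independent of them. Of 24 measured genes 13 fell and 1 rose, and the median was -1.13 (camera p = 2.24e-13, but p = 0.0963 with an estimated correlation). These values describe the chosen genes and leave a group change, and a part of the strain background in it, untested.

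Several genes of leucine, isoleucine and valine synthesis were lower as well. LEU1 fell by 2.81 (570 to 81.4 FPKM, limma adjusted p = 0.000307), the mitochondrial carrier OAC1 by 2.41 (adjusted p = 0.000571) and the aminotransferase BAT1 by 2.33 (adjusted p = 0.000776). A list of 13 genes, again written after some falls were seen, had 9 falls, 0 rises and a median of -1.20 (camera p = 3.59e-09, but p = 0.0889 with an estimated correlation). It also holds GDH1 (-1.38, among the 9 falls) and LEU3 (-0.12), which encode no enzyme of this synthesis. ILV2, ILV5 and LEU4 are members of the Gcn4-controlled list as well, so the 2 lists are not independent. The labels give the wild type and the null strains different LEU2 states, since LEU2 marks the tsa2 deletion, so an effect of the background was not excluded, and the list, chosen for its falls, leaves a group change untested. Genes repressed by good nitrogen sources were examined as another group, with GAP1 (-2.94), ASP3-1 (-2.69), which has near-identical copies, DAL80 (-2.64) and PUT1 (-2.42) lower. Of 30 genes 10 fell and 0 rose, and the median of -0.38 with members in both directions leaves a group change open (camera p = 2.36e-06, but p = 0.108 with an estimated correlation).

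Features near a chromosome end were called more often between null strains and wild type. Within 30 kb of an end 10.2% of 472 features passed against 6.18% of 6453 elsewhere (odds ratio 1.72, Fisher's exact p = 0.00129), and over features of 300 bp or more the odds ratio was 1.58 (Fisher's exact p = 0.0110). Neighbouring genes are not independent, so these p-values are too small. Of features of 300 bp or more other than deleted and marker genes, 6 were under 0.5 FPKM in both libraries of at least 1 strain and at 10 FPKM or more in the others. AIF1 and COS12, at 5.6 and 2.8 kb from an end, were near 0 in wild type, YLR302C in both null strains, YCL021W-A in D8B, and YBR012C and YBR013C in wild type and D8A.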
